A study of Mus musculus with 18 samples.

How the data were processed

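Total RNA of 18 samples of mouse immune cells was hybridised to Affymetrix 3' expression arrays, 6 at 0 h, 6 at 1 h and 6 at 4 h after a cell wall extract. The deposited values are signal intensities on a linear scale, one value per probe set and array, and the submitters' processing notes name MAS5 and GCOS, Affymetrix's software for turning probe cells into probe set signals, with no version. No aligner applies to arrays, and the settings of the signal calculation are not given in the sources used here. In the deposited intensity table the mean of the values between the 2nd and 98th percentile was 499.8 on each array, as a scaling of every array to a common trimmed mean leaves it. That scaling holds the trimmed mean fixed on each array, so a broad change in the distribution of signals between times appears as a shift of the median: the median signal lay between 86.2 and 108.1 on the arrays at 0 h and 1 h and between 74.7 and 87.5 at 4 h. Every column of the table was used.

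Each sample was put in its group by the time in its own label, and replicates were numbered in accession order, so the numbers do not pair samples across times. The labels give no genotype, strain, cell type, animal or batch for any sample. The titles carry an array code, and the codes fall into 3 ranges with 2 arrays of each time in every range, which were planned as a block before the data were examined. Residuals from the means of the times were grouped by these ranges: for 18 of 18 arrays the best correlated array of another time was of the same range, the median residual correlation was 0.343 within a range and -0.145 between ranges, and the first and second principal components of the residuals held 24.3% and 16.4% of the variance. No pair of arrays had identical values, and the log2 correlation of arrays of the same time lay between 0.918 and 0.97.

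Probe sets were named with the platform annotation supplied for this work, and its gene identifiers were matched to the RefSeq gene table of the assembly GRCm38.p6, used for names alone. Of 45101 probe sets, 64 are controls, 34945 carry a single gene symbol, of which 34741 matched the table, 932 carry several and 9160 none. Probe sets with several symbols or none were tested and counted, 4116 of them, but not named. No genome sequence was used and no coordinates are given. Of the 384 genes in the fixed lists 350 have a probe set with a single symbol, and the rest are not analysed here.

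Values were taken as log2(signal + 16), with no further normalization. A probe set was kept if it lay above the median of its own array on at least 4 of the 18 arrays, which left 25804 probe sets (57.3%) for 11733 genes. R 4.3.3 and limma 3.58.1 fitted a mean per time over all 18 arrays (lmFit and eBayes), so that the 3 times share an estimate of the spread, and p-values were adjusted over probe sets by Benjamini-Hochberg with a threshold of 0.05. "Rose", "fell" and "changed" refer to this threshold. A gene was represented by its kept probe set with the highest mean log2 value. The fit was tested on simulated data of the 4 h against 0 h comparison over 25804 probe sets, with 50 changed at each size. It recovered 12% of the 1.5-fold, 54% of the 2-fold, 96% of the 4-fold and 100% of the 8-fold changes. There were 4 false calls and 0 calls in the wrong direction. The simulated noise was independent between probe sets and arrays, with no grouping by code range. These rates need not hold for the real arrays, whose residuals group by range.

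The 24 gene lists were fixed before the data were examined: inflammatory cytokines, IL-10 and its pathway, chemokines, NF-kB subunits and feedback, immediate early genes, MAP kinase feedback, interferon response, pattern recognition receptors and adaptors, restraint of TLR signalling, antigen presentation and costimulation, antimicrobial and inflammatory effectors, cell cycle, glycolysis and HIF-1 targets, cholesterol synthesis, survival and cell death, uptake receptors, and markers of macrophages, dendritic cells, neutrophils, T cells, B cells, NK cells, stroma and erythroid cells. The 19 lists with at least 5 measured genes were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the residuals. Some genes stand in more than 1 list.

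The genes named in the text were chosen by a rule fixed before the data were examined: Il10 and Tlr2 from the title; the 10 largest rises and the 10 largest falls past the threshold at 1 h and at 4 h against 0 h, and the 5 and 5 between 1 h and 4 h; and for each list up to 4 members past the threshold with the largest change in a comparison, or the 2 brightest where none passed. The remaining genes of the title are not analysed here. Where another probe set of a gene named in the text moved the opposite way past the threshold, this is said here: for Traf1 between 1 h and 4 h a further probe set rose by 2.40 (adjusted p = 0.012), while the representative had a log2 fold change of -0.27 (adjusted p = 0.753), and for Cflar in that comparison a further probe set had a log2 fold change of -0.90 (adjusted p = 0.0171), while the representative rose by 1.42 (adjusted p = 0.0115). For Il10 and Tlr2 the means of log2 values were also compared by two-sided exact permutation tests over all 924 assignments of 12 arrays. The assignments ignore the code ranges, by which the residuals group.

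Alternatives planned before the data were examined were pseudocounts of 1 and 64, no filter and a filter on the mean, quantile normalization, centring each array on its median, the code range as a block, runs of codes as a block on 12 arrays, eBayes with trend and robust settings, a fit of the compared times alone, leaving out each array in turn, and for the lists the estimated correlation and the mean of a gene's probe sets. Ratios of the 3' to the 5' probe set of actin and Gapdh, which rise when RNA is degraded, were used as a sign of RNA quality: the median actin ratio was 1.30 over the 18 arrays, and t1h replicate 3 (2.44) and t4h replicate 2 (1.98) stood above the others, of which the highest was 1.56. Those 2 arrays were left out in an alternative chosen after seeing the data. The estimated correlation was also combined with the code range as a block, a choice made at the same stage. The spikes of the hybridisation mix, read by 18 control probe sets, were averaged on the log2 scale per array. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.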

Results

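The series measured gene expression in mouse immune cells before and after treatment with a cell wall extract, a preparation of bacterial or other microbial wall material whose source the labels do not give. RNA from 18 samples was hybridised to 18 Affymetrix arrays, of which 6 were taken at 0 h as controls, 6 at 1 h and 6 at 4 h after treatment. The title of the series names TLR2, a surface receptor for bacterial lipoproteins, 2 further members of a signalling axis, and the production of IL-10, a cytokine that restrains inflammation. The design text says that the mice were knockouts, but no label gives a genotype, strain or cell type for any sample. The samples were therefore compared by time alone. Any difference in genotype adds to the spread within a time. If the genotypes were not balanced over the times, such a difference would also shift the comparisons. Each fold change is an average over samples that may differ in genotype. Nothing in the labels says that the 6 samples of a time came from separate animals or cultures. The p-values therefore measure the spread between these samples, which may be technical in part. Signals are on a linear scale and fold changes were computed from log2(signal + 16), which understates the changes of dim genes. After a filter on dim probe sets, 25804 probe sets for 11733 named genes were tested with limma. The number of arrays limits the precision of every value below.

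The markers of cell types fixed before the data were examined showed which transcripts were abundant. Of 14 macrophage markers, 13 were measured, and their mean log2 value on single arrays lay between 12.67 and 13.5. Only 2 of 12 T cell markers, 1 of 8 B cell markers, 2 of 8 NK cell markers, 4 of 10 dendritic cell markers and 2 of 8 erythroid markers passed the filter on dim probe sets. Of 12 neutrophil markers 7 passed, and of 8 stromal markers, which are collagens and other genes of fibroblasts, 7 passed. In these counts a marker with no probe set of a single symbol would also stand as not passed. The titles of the samples carry an array code, whose meaning the labels do not give. The codes fall into the ranges 12 to 22, 32 to 37 and 44 to 54, each with 2 arrays of every time. The mean log2 value of the stromal markers was 7.30 ± 0.22 (SD, n = 6 arrays) in the range 12 to 22, 8.86 ± 0.27 in the range 32 to 37 and 10.38 ± 0.22 in the range 44 to 54. The median stromal marker was 4.07-fold higher in 32 to 37 and 13.8-fold higher in 44 to 54 than in 12 to 22. Of the 7 markers, 6 and 7 passed adjusted p 0.05 by limma. The neutrophil markers ran the other way, at 8.91 ± 0.22, 8.14 ± 0.27 and 7.10 ± 0.33. The cell cycle genes stood at 10.59 ± 0.59, 11.40 ± 0.21 and 9.87 ± 0.32. The macrophage markers stood at 12.96 ± 0.14, 13.00 ± 0.23 and 13.22 ± 0.19. As every range holds all 3 times in equal numbers, these differences do not separate the times, but they widen the spread within a time.

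**Figure D1:**
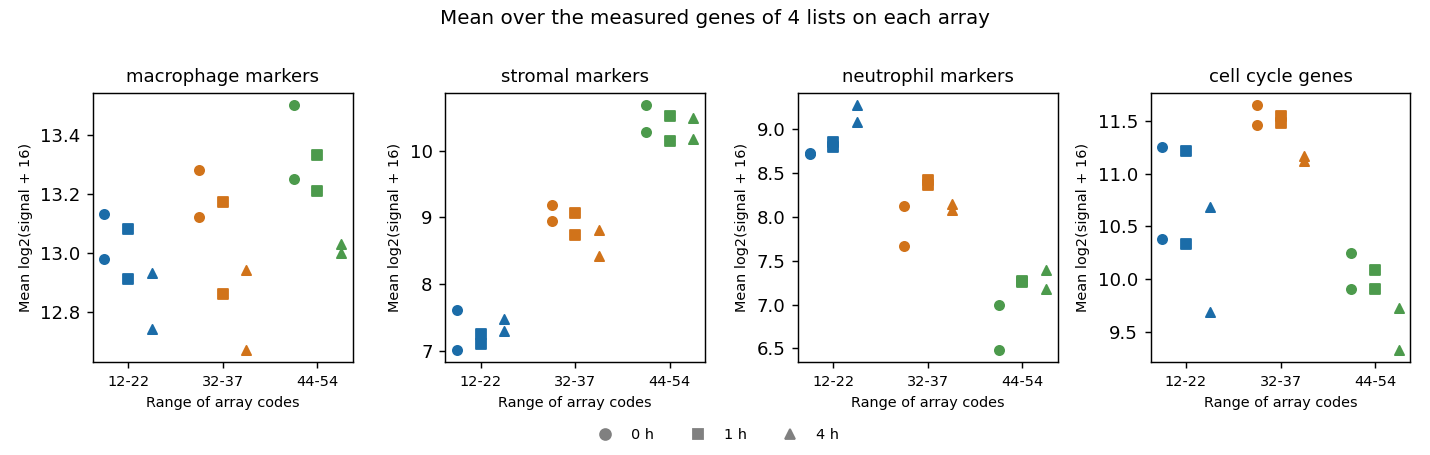
Mean log2(signal + 16) over the measured genes of 4 marker lists (vertical axes, each panel on its own scale) on each of the 18 arrays, by range of array codes (horizontal axis, colour) and time (circles 0 h, squares 1 h, triangles 4 h). The stromal means of the 3 ranges do not overlap and rise from 7.30 to 8.86 and 10.38, while the macrophage means differ by less, from 12.96 to 13.22.

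Il10, which encodes the cytokine named in the title, rose within 1 h and stayed high at 4 h. Its signal was 197 ± 119 (SD, n = 6) at 0 h, 1448 ± 681 at 1 h and 1722 ± 950 at 4 h. The log2 fold change against 0 h was 2.84 ± 0.57 (SE) at 1 h (limma, adjusted p = 0.0196; exact permutation test, two-sided p = 0.00649). At 4 h it was 3.11 ± 0.57 (limma, adjusted p = 4.13e-04; exact permutation test, two-sided p = 0.00216, the smallest that 6 against 6 arrays allow). Between 1 h and 4 h the log2 fold change was 0.27 ± 0.57 (limma, adjusted p = 0.773; exact permutation p = 0.63). Tlr2 was already bright at 0 h, with a signal of 5795 ± 2393, and reached 14300 ± 5770 at 1 h and 23530 ± 5271 at 4 h. Its log2 fold change at 1 h was 1.27 ± 0.32, which did not pass the adjusted threshold of the limma fit (adjusted p = 0.0859; exact permutation p = 0.0173). At 4 h Tlr2 rose by 2.09 ± 0.32 (limma, adjusted p = 7.98e-05; exact permutation p = 0.00216). Between 1 h and 4 h the log2 fold change of Tlr2 was 0.83 ± 0.32 (limma, adjusted p = 0.0678; exact permutation p = 0.00866). The 6 exact tests of these genes have Benjamini-Hochberg adjusted p from 0.00648 to 0.63. With the range of array codes as a block, Tlr2 passed at 1 h (limma, adjusted p = 0.0325) and between 1 h and 4 h (adjusted p = 0.0308), and Il10 passed at 1 h with adjusted p = 0.0127. Within the ranges 12 to 22, 32 to 37 and 44 to 54, the log2 fold change of Il10 at 4 h was 1.45, 4.95 and 2.93, and that of Tlr2 was 3.09, 1.68 and 1.51. At 1 h the values were 0.91, 4.92 and 2.69 for Il10 and 1.08, 1.45 and 1.28 for Tlr2. The differences between ranges at 4 h did not pass the threshold (limma, adjusted p = 0.179 for Il10 and 0.219 for Tlr2). The rise of Il10 at 1 h lost its call in 8 of 31 alternative settings. Of these, 5 left out t0 replicate 3 or t1h replicate 1, 2, 3 or 4, where the adjusted p by limma was 0.0581, 0.0593, 0.0644, 0.0575 and 0.0615. Over all settings but a fit on 12 arrays (0.512) the adjusted p ran from 0.001 to 0.0742. The other 2 genes of the axis in the title are not analysed here.

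**Figure D2:**
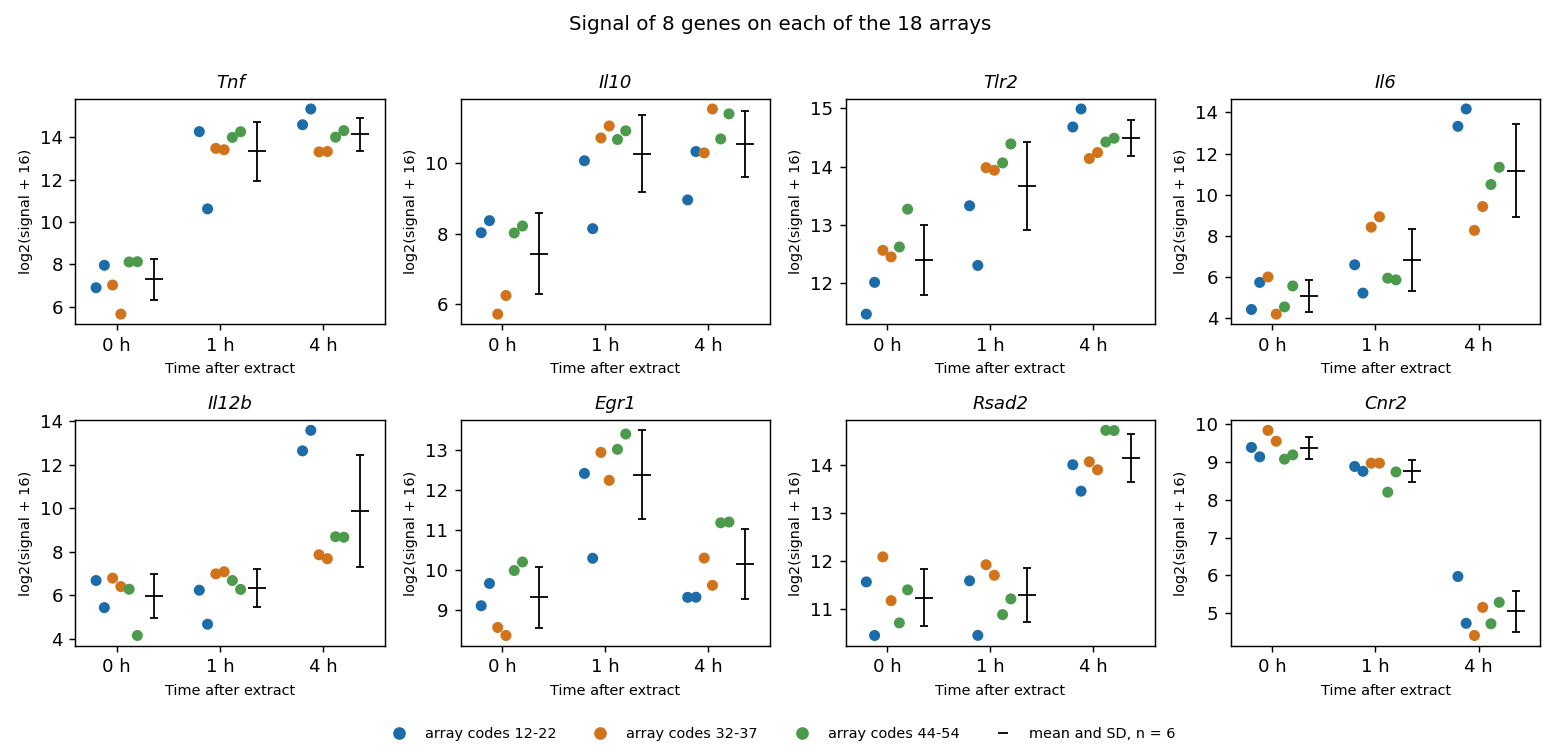
Signal of 8 genes as log2(signal + 16) (vertical axes, each panel on its own scale) on each of the 18 arrays by time after the extract (horizontal axis), coloured by range of array codes, with the mean and SD of each time beside the points (n = 6). Tnf, Il10 and Egr1 rose at 1 h, Rsad2 and Il6 rose at 4 h, and Cnr2 fell at 4 h; one array of the range 12 to 22 lies lowest for Tnf, Il10 and Egr1 at 1 h, with a Tnf signal of 1557.

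The first comparison asks what changed in the first hour. Tnf, which encodes a central inflammatory cytokine, went from a signal of 168 ± 96.7 (SD, n = 6) to 13210 ± 6869, a log2 fold change of 6.04 ± 0.57 (SE; limma, adjusted p = 4.26e-05). Cxcl1 and Cxcl2, which encode chemokines that attract neutrophils, rose by 5.81 ± 0.59 and 5.06 ± 0.42. Tnfsf9, a TNF family ligand, rose by 5.05 ± 0.62, and Il1b, which encodes interleukin 1 beta, by 4.47 ± 1.01 (limma, adjusted p = 0.0448). The other large rises were those of Egr2 (4.12), an early transcription factor, Acod1 (4.09), the enzyme that makes itaconate, Tnfaip3 (4.03), a ubiquitin editing enzyme that limits NF-kB signalling, Ccl3 (3.87), a chemokine, and Socs3 (3.82), an inhibitor of cytokine receptor signalling. By their representative probe set 4 genes fell: E330020D12Rik (log2 fold change -1.32), Sftpb (-1.32), and the zinc finger genes Zfp472 (-0.90) and Zfp157 (-0.90). Counting every probe set of a gene, 94 genes rose and 22 fell.

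By gene list, the immediate early genes, which respond to signalling without new protein synthesis, held the most rises at 1 h, with 10 of 25 measured members up and none down (17 up adjusted over the list alone). Besides Egr2 they included Egr1 (3.07 ± 0.49) and Nr4a1 (2.26 ± 0.42). Of the chemokines, 7 of 19 rose (9 adjusted over the list alone), among them Ccl4 (2.44 ± 0.41). Of the NF-kB subunits and feedback genes, 7 of 18 rose (17 adjusted over the list alone), among them Traf1 (3.36 ± 0.52), a signalling adaptor, and Nfkbiz (2.96 ± 0.48), a nuclear IkB protein. The MAP kinase feedback list had 3 of 14 up (5 adjusted over the list alone), all phosphatases of MAP kinases, Dusp2 (3.61 ± 0.62), Dusp1 (2.35 ± 0.28) and Dusp4 (2.05 ± 0.34). Of the inflammatory cytokines 3 of 14 rose, namely Tnf, Tnfsf9 and Il1b (5 adjusted over the list alone), and of the IL-10 pathway 2 of 14, Il10 and Socs3 (6 adjusted over the list alone). The list of restraint of TLR signalling had 2 of 10 up (2 adjusted over the list alone), Tnfaip3 and Socs3, which also stand in the NF-kB and IL-10 lists respectively. The survival and cell death list had 3 of 15 up (6 adjusted over the list alone), among them the stress genes Gadd45a (2.36 ± 0.43) and Gadd45b (1.56 ± 0.33). The antimicrobial effectors had 2 of 18 up, Acod1 and Sod2 (1.04 ± 0.21), the mitochondrial superoxide dismutase (7 adjusted over the list alone). These 9 lists shifted upward against the other genes by limma's camera with its preset correlation, with adjusted p from 3.66e-39 for the NF-kB list to 6.07e-06 for the restraint of TLR signalling. With an estimated correlation the adjusted p of the 9 ran from 4.58e-04 for the immediate early genes to 0.0159 for the IL-10 pathway. In the antigen presentation list, Cd83 (3.16 ± 0.55) and the adhesion gene Icam1 (2.07 ± 0.41) rose out of 18 (2 adjusted over the list alone). The camera adjusted p was 0.0445, with adjusted p = 0.456 with an estimated correlation. In the interferon response list only Irf1 (2.08 ± 0.41), which encodes a transcription factor, rose out of 25 (1 adjusted over the list alone). That list's camera adjusted p was 0.93, with an upward mean (0.02) and a downward median (-0.06). No member passed among the pattern recognition receptors and adaptors (20 measured), cell cycle (24), glycolysis (16), cholesterol synthesis (13), uptake receptors (14), macrophage (13), neutrophil (7) or stromal markers (7). Adjusted over the list alone, 1 pattern recognition receptor or adaptor passed and no member of the others. The camera adjusted p of these lists ran from 0.135 to 0.879. The neutrophil list had adjusted p = 0.698 with an estimated correlation. Blocked by code range it passed upward (camera adjusted p = 0.00442, and adjusted p = 0.033 with an estimated correlation), while no single marker did. In that fit 5 of the MAP kinase feedback genes and 5 of the antimicrobial effectors rose.

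Over all probe sets, 194 of 25804 changed at 1 h by limma at adjusted p 0.05, 158 up and 36 down, of which 140 and 18 changed at least 2-fold. Without adjustment, 1765 probe sets had p under 0.05. With the code range as a block the count was 339 (267 up, 72 down). Within the ranges 12 to 22, 32 to 37 and 44 to 54, limma called 0, 167 and 132 rises and 0, 20 and 19 falls, with 920 probe sets of the first range at an unadjusted p under 0.05. The test of the difference between ranges called 0 (919 unadjusted). A single array, t1h replicate 6 of the range 12 to 22, carried little of the response, and without it the count was 418 (309 up, 109 down). Without t1h replicate 1, 2, 3 or 4 the count was 118, 108, 125 and 118. A further fit took runs of codes as a block. Each run held 1 array of every time with neighbouring codes, such as 12, 14 and 16, though no label pairs these arrays. The range 44 to 54 has no such runs and was left out. In this fit on 12 arrays no gene passed at 1 h (1969 probe sets at an unadjusted p under 0.05). In each other alternative the calls of Tnf, Cxcl1, Cxcl2, Tnfsf9, Tnfaip3, Socs3 and Dusp1 held (highest adjusted p 0.00722 by limma). Of all 31 alternatives, the call was lost in 22 for Zfp157, 21 for Il1b, 19 for E330020D12Rik and 15 for Zfp472, of which 15, 16, 13 and 10 left out a single array (limma, adjusted p up to 0.156 outside the fit on 12 arrays). It was lost in 11 for Gadd45b, 10 for Sod2, 9 for Icam1, 8 for Sftpb, 5 for Irf1, and 2 each for Cd83 and Nr4a1.

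The second comparison asks what had changed by 4 h. Chemokines, cytokines and antimicrobial genes were raised up to 198-fold. Cxcl3, a neutrophil chemokine, went from 107 ± 26.6 (SD, n = 6) to 24840 ± 7388, a log2 fold change of 7.63 ± 0.53 (SE; limma, adjusted p = 3.15e-08). Acod1 rose by 7.30 ± 0.65, Tnf by 6.85 ± 0.57 and Cxcl1 by 6.78 ± 0.59. Saa3, an acute phase protein, rose by 6.46 ± 0.38 and Ccl3 by 6.26 ± 0.62. Further rises were those of Il6 by 6.08 ± 0.86, Il1b by 5.78 ± 1.01, Ccl4 by 5.67 ± 0.41 and Hcar2, a receptor for ketone bodies and niacin, by 5.65 ± 0.49. Among the falls, Abcd2, a peroxisomal transporter of fatty acids, went from a signal of 601 ± 310 to 5.64 ± 4.18. Its log2 fold change was -4.70 ± 0.41 (limma, adjusted p = 2.43e-07). Others of the 10 largest falls were those of the cannabinoid receptor Cnr2 (-4.31 ± 0.22), Rgs2 (-4.21 ± 0.35), a regulator of G protein signalling, the chemokine receptor Cxcr4 (-3.78 ± 0.44), Arrdc3 (-3.74 ± 0.23), an arrestin domain protein, Lpar6 (-3.62 ± 0.23), a receptor for lysophosphatidic acid, and the oxysterol receptor Gpr183 (-3.32 ± 0.29). The remaining 3 of the 10 largest falls were Gcnt1 (-3.50 ± 0.25), a glycosyltransferase, Cytip (-3.36 ± 0.74), a regulator of cell adhesion, and Bmf (-3.33 ± 0.27), a promoter of apoptosis.

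**Figure D3:**
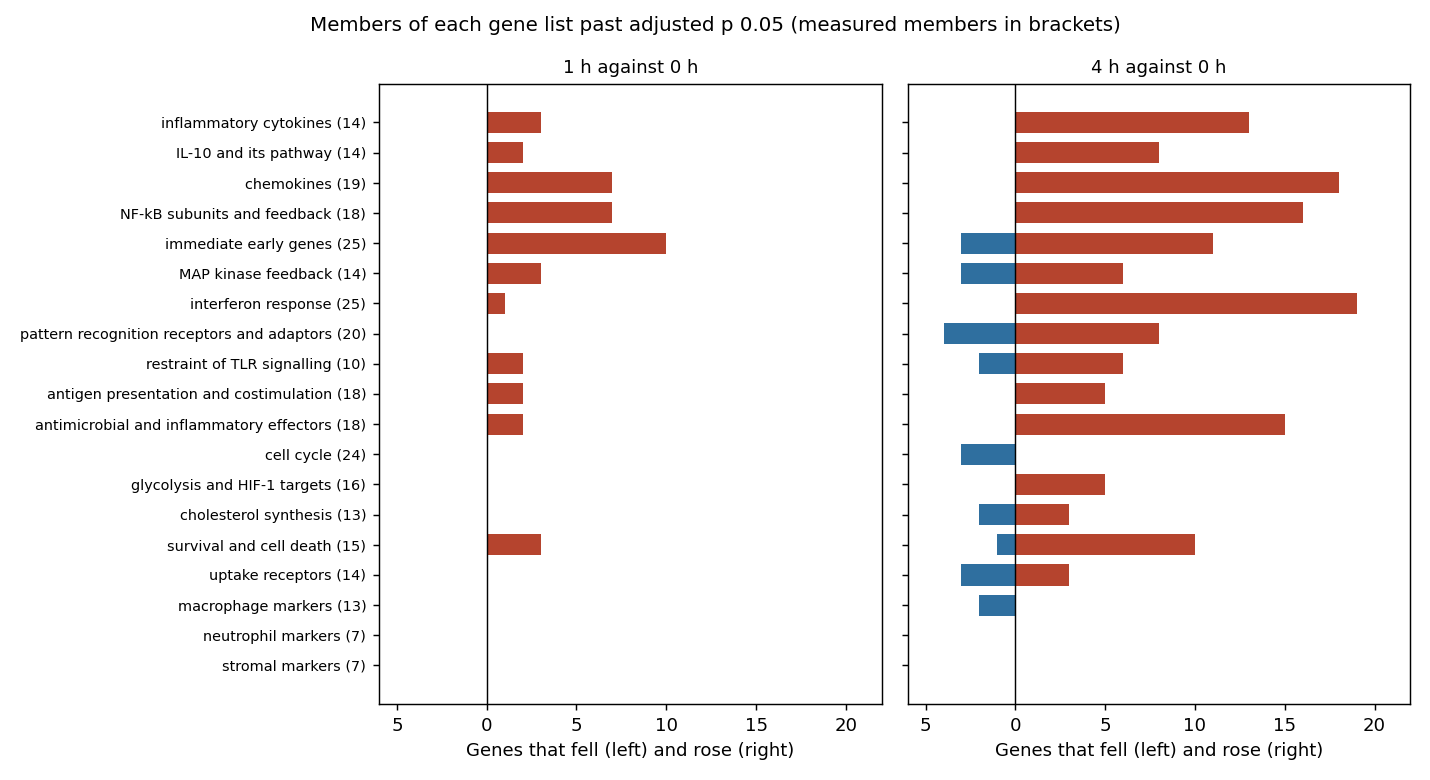
Number of genes past adjusted p 0.05 (limma) in each of the 19 tested gene lists at 1 h and at 4 h against 0 h (horizontal axis, falls to the left in blue and rises to the right in red), with the number of measured members in brackets. At 4 h, 18 of 19 chemokines, 19 of 25 interferon response genes and 16 of 18 NF-kB genes rose, against 7, 1 and 7 at 1 h.

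At 4 h, of the chemokines 18 of 19 rose and of the inflammatory cytokines 13 of 14, the latter including Il1a (5.24 ± 0.71) (18 and 14 adjusted over the list alone). Of the NF-kB list 16 of 18 rose (17 adjusted over the list alone), with Tnfaip3 (4.67 ± 0.48), Zc3h12a (3.03 ± 0.34), a nuclease that degrades cytokine messages, and Nfkb2 (2.92 ± 0.33). Of the antimicrobial and inflammatory effectors 15 of 18 rose (15 adjusted over the list alone), with Ptgs2 (5.58 ± 0.73), the inducible cyclooxygenase, and Lcn2 (4.66 ± 0.54), which binds bacterial siderophores. The IL-10 pathway had 8 of 14 up (8 adjusted over the list alone), including Il1rn (4.42 ± 0.49), the interleukin 1 receptor antagonist, and Socs3 (4.86 ± 0.43). The list of restraint of TLR signalling had 6 of 10 up and 2 down (6 and 2 adjusted over the list alone). Irak3, an inhibitory kinase homologue, rose by 2.31 ± 0.23, while for Inpp5d, a phosphatase, the log2 fold change was -1.84 ± 0.16. The survival and cell death list had 10 of 15 up and 1 down (10 and 2 adjusted over the list alone), with members of both kinds among the rises: Fas (3.60 ± 0.54), a death receptor, and Casp4 (2.83 ± 0.31), an inflammatory caspase, and Cflar (3.11 ± 0.38) and Bcl2l1 (1.41 ± 0.24), which inhibit apoptosis. These 7 lists passed camera with an estimated correlation, at adjusted p from 0.0211 for the chemokines and the effectors to 0.0466 for the IL-10 pathway. With the preset correlation their adjusted p ran from 9.63e-18 to 0.00142. With the code range as a block and an estimated correlation, none of the 19 lists passed, and the adjusted p of these 7 ran from 0.0687 to 0.0731.

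The interferon response, of which 1 gene had passed at 1 h, had 19 of 25 members up at 4 h (19 adjusted over the list alone), with Gbp2 (2.99 ± 0.45), Rsad2 (2.92 ± 0.30), Ifit1 (2.88 ± 0.33) and Mx2 (2.83 ± 0.49), all known as interferon induced. The camera adjusted p was 9.20e-13, and adjusted p = 0.123 with an estimated correlation. The immediate early genes had 11 of 25 up and 3 down (13 and 3 adjusted over the list alone), with Nr4a3 (4.14 ± 0.78) and Egr2 (3.82 ± 0.57) up, and Fos (-1.31 ± 0.30) and Klf2 (-1.56 ± 0.27) down. The camera adjusted p was 1.44e-05, and adjusted p = 0.0884 with an estimated correlation. The MAP kinase feedback list had 6 of 14 up and 3 down (6 and 3 adjusted over the list alone), with Dusp2 (3.88 ± 0.62) and Dusp16 (3.70 ± 0.42) up and Dusp6 (-1.68 ± 0.41) down. The camera adjusted p was 0.00193, and adjusted p = 0.0876 with an estimated correlation. Receptors for microbial patterns moved apart, with 8 of 20 up and 4 down (8 and 4 adjusted over the list alone). Besides Tlr2, Tlr1 (2.46 ± 0.40), the partner of TLR2 in sensing triacylated lipoproteins, and the kinase homologue Irak2 (1.58 ± 0.27) rose, while Tlr8 (-2.34 ± 0.42) and Tlr4 (-1.10 ± 0.21), the receptor for lipopolysaccharide, fell. Here camera gave adjusted p = 0.00432, and adjusted p = 0.0884 with an estimated correlation. The antigen presentation and costimulation list had 5 of 18 up (5 adjusted over the list alone), with the costimulatory receptor Cd40 (4.21 ± 0.42), Icam1 (3.55 ± 0.41) and Cd83 (3.45 ± 0.55). Here camera gave adjusted p = 0.00284, and adjusted p = 0.191 with an estimated correlation. The glycolysis and HIF-1 list had 5 of 16 up (5 adjusted over the list alone), with the glucose transporter Slc2a1 (2.47 ± 0.25) and the glycolytic genes Pfkfb3 (2.47 ± 0.49), Pfkl (1.25 ± 0.18) and Hk2 (1.19 ± 0.27). Here camera gave adjusted p = 4.57e-04, and adjusted p = 0.172 with an estimated correlation. Blocked by code range, 8 of the 16 rose.

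Other lists did not pass camera at 4 h. The uptake receptors had 3 up and 3 down of 14 (3 and 3 adjusted over the list alone; camera adjusted p = 0.465; median log2 fold change -0.24, mean 0.26). The scavenger receptors Marco (4.21 ± 0.76) and Msr1 (1.82 ± 0.28) and the inhibitory Fc receptor Fcgr2b (3.24 ± 0.24) rose, and Mertk (-2.70 ± 0.34), a receptor for apoptotic cells, fell. Of the macrophage markers, 2 of 13 fell, Trem2 (-1.02 ± 0.16) and Cd163 (-1.01 ± 0.23), and none rose (0 and 2 adjusted over the list alone; camera adjusted p = 0.219). Of the cholesterol synthesis genes, Hmgcs1 (0.73 ± 0.20) and Cyp51 (0.85 ± 0.27) were among 3 of 13 that rose and Dhcr7 (-1.01 ± 0.20) was among 2 that fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.0781). Of the cell cycle genes 3 of 24 fell, Ccne2 (-1.10 ± 0.37), Tyms (-0.81 ± 0.23) and Mcm6 (-0.78 ± 0.28), with 0 adjusted over the list alone and camera adjusted p = 0.37. With each array centred on its median none of these 3 passed (adjusted p up to 0.203). The call of Mcm6 was also lost without t0 replicate 1, 3, 5 or 6 or t4h replicate 1, 3 or 4 (limma, highest adjusted p = 0.0966), and that of Ccne2 without t0 replicate 2, 3 or 5 or t4h replicate 3 or 6 (highest 0.0726). In the fit with the code range as a block, 11 of the 24 cell cycle genes fell, 5 of the cholesterol synthesis genes rose and 5 of the uptake receptors fell. The call of Cyp51 was lost without t4h replicate 3 (adjusted p = 0.0508). Without a block no neutrophil or stromal marker passed (7 measured in each; camera adjusted p = 0.219 and 0.595). With the code range as a block 3 neutrophil markers rose, S100a8 (1.17; limma, adjusted p = 0.00138), Mmp9 (0.97; 6.74e-04) and S100a9 (0.75; 0.038), while Mmp8 (-0.58; 0.00676) and the stromal marker Col1a2 (-0.51; 0.00875) fell. Their adjusted p without the block was 0.219, 0.21, 0.563, 0.24 and 0.723, and Mmp9 and S100a9 were named after their values were seen. The neutrophil list also passed camera with the block (adjusted p = 0.0448), but not with an estimated correlation (adjusted p = 0.108 with an estimated correlation and the block, and 0.608 without the block). The stromal median log2 fold change was -0.23, while camera's direction for that list was upward against other genes. Of the lists too short for camera, 1 of 4 dendritic cell markers rose, Itgax (1.66 ± 0.27), an integrin that some macrophages also carry. The single measured B cell marker, Cd79b, a part of the B cell receptor, fell (-1.44 ± 0.46; limma, adjusted p = 0.0214), but not with quantile normalization, with each array centred on its median or without t0 replicate 5 (adjusted p = 0.0778, 0.0705 and 0.0511). No T cell, NK cell or erythroid marker passed at 1 h or 4 h (2 measured in each).

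Over all probe sets, 8532 of 25804 changed at 4 h by limma, 2563 up and 5969 down, with 1224 and 2049 changed at least 2-fold. The median log2 fold change of all probe sets was -0.22, so the signals as deposited put the typical probe set below its level at 0 h. Relative to that shift, with each array centred on its median, 4180 rose and 2894 fell, a share of falls of 40.9%. With quantile normalization falls were 55.0% of the calls, against 70.0% in the deposited scale. No called change of the genes named above turned direction under these scalings. With the code range as a block 11065 changed (3242 up, 7823 down), and within the ranges 12 to 22, 32 to 37 and 44 to 54 the rises and falls were 1874 and 3386, 1595 and 2313, and 1650 and 3081.

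The third comparison asks what distinguished 4 h from 1 h. The largest rises were those of Saa3 by 5.19 ± 0.38 (limma, adjusted p = 9.08e-08), Cxcl3 by 4.53 ± 0.53 and Il6 by 4.34 ± 0.86. Itgb8, an integrin subunit that activates TGF-beta, rose by 4.30 ± 0.38, and Ccl5, a chemokine for T cells and monocytes, by 4.27 ± 0.63. The largest falls were again those of Abcd2 (-4.27 ± 0.41), Cnr2 (-3.70 ± 0.22), Cxcr4 (-3.63 ± 0.44), Gpr183 (-3.28 ± 0.29) and Gcnt1 (-3.28 ± 0.25). Of 25 immediate early genes 9 fell and 3 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.601). They included Fos (-2.28 ± 0.30), Egr1 (-2.23 ± 0.49), Klf2 (-2.01 ± 0.27) and Nr4a1 (-1.96 ± 0.42), transcription factors that fell. Of the interferon response genes 18 of 25 rose (19 adjusted over the list alone), with Mx2 (3.37 ± 0.49), Ifit1 (2.95 ± 0.33), Rsad2 (2.86 ± 0.30) and Gbp2 (2.81 ± 0.45). Of the chemokines 15 of 19 rose (15 adjusted over the list alone), of the antimicrobial effectors 12 of 18 (15 adjusted over the list alone) and of the cytokines 7 of 14 (9 adjusted over the list alone). Within the ranges 12 to 22, 32 to 37 and 44 to 54 the mean log2 fold change of the cytokines was 3.31, 0.08 and 1.21. That of the chemokines was 3.37, 1.02 and 1.72, and that of the effectors 2.61, 1.42 and 1.67. For the interferon list it was 1.54, 0.795 and 2.18. The first range holds t1h replicate 6, which carried little of the response at 1 h. Differences between ranges were not tested for whole lists. In the IL-10 pathway 2 of 14 rose and Il10ra, the ligand binding chain of the IL-10 receptor, fell with a log2 fold change of -1.06 ± 0.23 (4 up and 1 down adjusted over the list alone). When the code range was a block, 7 genes of the IL-10 pathway and 6 immediate early genes rose, and 7 of 24 cell cycle genes fell, of which 0 passed without it. Of the 19 lists 10 passed limma's camera with its preset correlation and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. With an estimated correlation the interferon, chemokine, effector, cytokine and IL-10 lists had adjusted p = 0.182, 0.108, 0.0576, 0.182 and 0.182.

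Several of these changes differed between the ranges of array codes. The fold between 1 h and 4 h differed for Il6 (limma, adjusted p = 0.00873), Il12b (0.00905), which encodes a subunit of interleukins 12 and 23, and Ccl5 (0.0228). The log2 fold change of Il6 was 7.83 in the range 12 to 22, 0.17 in 32 to 37 and 5.01 in 44 to 54. That of Il12b was 7.65, 0.74 and 2.20, and that of Ccl5 was 6.58, 1.77 and 4.47. At 4 h the signal of Il12b was 6337 and 12190 on the arrays of the range 12 to 22 and between 189 and 397 on the other 4. The fall of Cxcr4 from 1 h to 4 h also differed between ranges (-5.26, -2.40 and -3.22; limma, adjusted p = 0.0401), and so did the rise of Marco (5.10, 1.74 and 5.55; adjusted p = 0.0221). The same test passed for Dusp16 (4.58, 1.58 and 1.93), Dusp6 (-3.18, -0.51 and -0.55), Fas (4.57, 1.43 and 2.79) and Cd40 (4.70, 1.98 and 2.33). It also passed for Rgs2 (-4.72, -2.63 and -1.91) and Gadd45a (1.71, -1.09 and -1.09), and the adjusted p of these 6 genes ran from 0.00665 to 0.0334. Of the 2 arrays at 1 h in the range 12 to 22, 1 is t1h replicate 6, which carried little of the response at 1 h and enters each of these folds. The range 32 to 37 holds both arrays with high actin ratios, t1h replicate 3 (2.44) and t4h replicate 2 (1.98). They enter the folds of that range, and no test of these genes without them is given here. For Gadd45a the log2 fold change at 1 h against 0 h was 0.82, 3.26 and 3.01 (difference between ranges, limma, adjusted p = 0.843). At 4 h against 0 h it was 2.52, 2.17 and 1.92 (adjusted p = 0.928). Against 0 h, the change at 4 h differed between ranges for Ccl5 (7.24, 2.06 and 5.02; limma, adjusted p = 0.0195), Marco (5.14, 1.83 and 5.67; 0.0286) and Il12b (7.05, 1.18 and 3.46; 0.0288), and did not pass for the other 8 of these genes. The stromal and neutrophil markers also differed along these ranges, as given above.

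Over all probe sets, 6286 changed between 1 h and 4 h by limma, 1988 up and 4298 down, with 867 and 1429 changed at least 2-fold. The median log2 fold change was -0.17 and falls were 68.4% of the calls. With each array centred on its median 3456 rose and 2065 fell, a share of falls of 37.4% (52.9% with quantile normalization). With the code range as a block 8763 changed (2740 up, 6023 down), and within the ranges the rises and falls were 1679 and 3028, 973 and 1468, and 1078 and 1836.

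Most probe sets that had risen at 1 h were still up at 4 h. Of the 158 probe sets that rose at 1 h, 139 were also up at 4 h against 0 h, where 15.7 would be shared by independent lists of these lengths. Of the 36 that fell at 1 h, 31 were also down at 4 h, against 8.33 for independent lists. Simulated unchanged groups set against the same controls had at most 1 call at 1 h and 0 at 4 h, so they give no baseline for these counts. With the 6 controls split into 3 and 3, so that the comparisons share no array, a median of 45 of 51.5 rises and of 1.5 of 2.5 falls called at 1 h were shared. The covariance of the fold changes across probe sets, which are not independent replicates, was 0.147, against 0.0433 simulated from shared controls alone and 0.106 with split controls. The correlation was 0.564, against 0.501 simulated. Of the 158 probe sets that rose at 1 h, 52 were higher at 4 h than at 1 h, 21 were lower, and for 85 the difference did not pass the threshold.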

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

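Of the tests in this part, those on t1h replicate 6, on the share of macrophages, on genotype, on the hybridisation spikes and on the place of the range 44 to 54, the splits within code ranges and the count of splits for the lists between 1 h and 4 h with an estimated correlation were chosen after the result was seen, and so were the alternatives for the difference between code ranges. Chance alone puts about 1 in 20 groups of samples past the test for a sample far from the others (Dixon's ratio). Here 41 of 315 groups were past it, over 97 genes and several measures per array, and 23 of the 41 were low values of t1h replicate 6.

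On t1h replicate 6 the signals of 23 genes lay far below those of the other 5 arrays at 1 h. All but Il1a, Fos and Il12b had risen at 1 h over the 6 arrays. The values were 1557 for Tnf, 1130 for Cxcl1, 7880 for Cxcl2, 626.6 for Tnfsf9, 281.7 for Il1b, 220.2 for Acod1, 1498 for Tnfaip3, 633.9 for Ccl3, 1857 for Socs3, 266.8 for Il10, 383.9 for Ccl4, 3120 for Nfkbiz, 389.9 for Traf1, 1242 for Egr1, 7678 for Dusp1, 92.02 for Dusp2, 480.2 for Gadd45a, 856.3 for Cd83, 1683 for Icam1, 905.8 for Irf1, 7.766 for Il1a, 11360 for Fos and 9.517 for Il12b.

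The weak response of that array was weighed against technical explanations. Over the 309 probe sets that rose at 1 h without it, its slope on the response of the other arrays was 0.14, where the other arrays at 1 h had slopes from 0.744 to 1.12 and the arrays at 0 h, each against the other 5, from -0.138 to 0.116. Degraded RNA is argued against, as the actin ratio of the array was 1.34, near the median of 1.30 and below the highest, 2.44. A sample of 0 h under a label of 1 h cannot be told apart from a weak or late response by this slope, which lies just above the arrays at 0 h; its Tnf signal of 1557 exceeds the highest at 0 h, 263.3, and 6 of the 309 probe sets lay over 2-fold above every array at 0 h, against at most 2 for any array at 0 h set against the others. A difference in genotype between mice stays open and untested, since no label gives a genotype.

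At 4 h more probe sets fell than rose, and the scaling of the arrays to a common trimmed mean was weighed as an explanation. With each array centred on its median instead, falls were 40.9% of the calls, but centring brings the median to near 0 by construction and so favours this outcome. With quantile normalization falls were 55%, between the bounds set in advance, so an intensity-dependent difference between arrays cannot be told apart from a true majority of falls by that test. The hybridisation spikes, foreign transcripts of 18 probe sets, changed by -0.29 ± 0.17 (SE) on the log2 scale from 0 h to 4 h (exact permutation test, two-sided p = 0.128), a spread that excludes neither a shift like the -0.22 of the typical probe set nor none, so the scaling stays open. The biological explanation, a wider loss of transcripts at 4 h, was not tested, as the spikes are added to labelled RNA and do not measure RNA per cell.

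The response at 4 h differed between the ranges of array codes for 216 probe sets of 158 genes, by the test of the difference itself in limma (0 at 1 h, with 919 at an unadjusted p under 0.05), with the smallest adjusted p among genes, named after their values were seen, for Lhfpl2, with log2 fold changes at 4 h of -2.36, 1.49 and 0.00 in the ranges 12 to 22, 32 to 37 and 44 to 54, and Fnip2, with -1.11, 2.75 and 1.22. Scaling and intensity differences are argued against as the whole cause, as 196 probe sets differed after quantile normalization. A smaller share of macrophages in some ranges stays open. From 12 to 22 to 44 to 54 the stromal markers changed by 3.08 and the neutrophil markers by -1.82 on the log2 scale. Both changes went beyond the sums of their SDs (0.44 and 0.56). Fewer macrophages, with the other cells in fixed proportion, would raise both, but a change in the mix of those cells could hide this. The macrophage markers differed between ranges at 4 h by a median of 0.549 (upper quartile 0.707), where the 216 probe sets differed by 1.54. That value lay between the bounds set for this test. RNA quality in the range 32 to 37, which holds both arrays with high actin ratios, stays open: 94 probe sets differed without the 2 arrays, between the bounds set in advance, and few differed between 12 to 22 and 44 to 54 (0 alone, 2053 unadjusted, and 10 with all 18 arrays in the fit). The counts of 0 and 10 lay under the bound set in advance for RNA quality as the cause. Against a fault of that range alone, few also differed between 32 to 37 and 44 to 54 (0 alone, 1866 unadjusted, and 2 with all 18 arrays). With all 18 arrays, 12 to 22 against 32 to 37 gave 348. Over the 216 probe sets the response of 44 to 54 had a median place of 0.51 from 12 to 22 (0) to 32 to 37 (1). Its lower quartile of 0.225 keeps the place from deciding. A change in the stromal or neutrophil cells themselves was not tested and stays open, and so does a genotype shared by the arrays of a range, as 0 arrays have a label that names a genotype.

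Samples far from the others were also seen for Cxcl2 on t0 replicate 5 (268.1, low), Acod1 on t4h replicate 6 (35940, high), Zfp157 on t0 replicate 1 (592.0, high), Nr4a1 on t4h replicate 5 (318.3, low), Sod2 on t4h replicate 6 (37770, high) and Saa3 on t0 replicate 2 (585.6, high). The same held for Cnr2 on t1h replicate 1 (277.9, low), Tlr8 on t4h replicate 2 (129.0, low), Tlr4 on t1h replicate 4 (3369, high), Pfkl on t1h replicate 1 (879.6, low), Cd163 on t4h replicate 4 (88.45, high), Cyp51 on t4h replicate 5 (481.6, low) and Bcl2l1 on t1h replicate 4 (294.4, low). As about 1 in 20 groups pass this test by chance, chance cannot be excluded for these genes. Among measures per array, the median signal of t4h replicate 1 was high (87.5), the actin ratio was high on t1h replicate 3 (2.44) and t4h replicate 2 (1.98), and so was the Gapdh ratio (1.28 and 1.51).

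Other splits of the 12 arrays of each comparison were drawn, 100 with the real split among them. For the probe sets changed, 1 of the 100 splits gave as many in each comparison, the real one, so chance is unlikely. The real counts were 194, 8532 and 6286 for 1 h against 0 h, 4 h against 0 h and 4 h against 1 h, and the highest of the other splits 124, 1261 and 988. For the lists past the threshold with the preset correlation, 30, 21 and 39 of the 100 splits gave as many as the real 10, 13 and 10, with 17, 18 and 15 as the highest of the others, so chance cannot be excluded for those counts. With an estimated correlation, 2 of 100 splits gave as many as the real 9 lists at 1 h (highest other 9). For 4 h against 0 h, 1 of 100 gave as many as the real 7 (highest other 1). Chance is unlikely for these counts, though another split also reached 9 lists at 1 h. For 4 h against 1 h the real count was 0, which all 100 splits reach. As the arrays group by code range, 100 splits were also drawn within the ranges and fitted with the range as a block. For the probe sets changed, again 1 of the 100 gave as many, the real one, so chance is unlikely. The real counts were 339, 11065 and 8763, with 179, 3833 and 3485 as the highest of the others. For the lists with the preset correlation 14, 23 and 29 of the 100 gave as many as the real 11, 14 and 10, with 15, 16 and 15 as the highest of the others, so chance cannot be excluded. With an estimated correlation 2 of 100 gave as many as the real 10 lists at 1 h (highest other 10). Chance is unlikely there, though another split also reached 10 lists. At 4 h the real count was 0 against 0 h and 0 against 1 h, which all 100 splits reach. The shares of splits were not adjusted for the number of counts tested.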

How the results depend on the processing

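The alternatives without t1h replicate 3 and t4h replicate 2, with the code range as a block and without t1h replicate 6, with the code range as a block and an estimated correlation, and all those for the difference between code ranges were chosen after seeing the data; the others were planned. Over the named genes, 4143 of the recomputed values kept their direction and side of the threshold, 176 lost the call, 20 gained it (7 for Tlr2, the others for S100a8, S100a9, Mmp8, Mmp9 and Col1a2 with a block) and 0 reversed; over the lists the counts were 1790, 54, 37 and 0. Of the 176 lost calls, 33 came from runs of codes as a block, which uses 12 arrays.

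The count at 1 h (194 changed, 158 up, 36 down) was the least stable. It was 339 (267 up, 72 down) with the code range as a block, 104 (84, 20) with the compared times alone, 107 (86, 21) without the 2 arrays of highest actin ratio, 627 (418, 209) with the code range as a block and without t1h replicate 6, and 0 with runs of codes as a block on 12 arrays (0 up, 0 down; 1969 at an unadjusted p under 0.05); without a filter 23 fell. The overlap of 1 h and 4 h, 170 probe sets, became 286, 94, 98, 527 and 0 in those settings. The cause was not tested; fewer arrays enter all of these but the first and the fit without a filter, and the fit on 12 arrays also has another block. Leaving out each array in turn gave 108 (without t1h replicate 2) to 418 (without t1h replicate 6) changed probe sets, 95 to 309 up and 13 to 109 down. Besides those 2 arrays, t1h replicates 1, 3 and 4 moved it by over 1.5 times (118, 125 and 118). So did t0 replicates 1, 3, 4, 5 and 6 for the falls alone (17, 23, 15, 17 and 19). At 4 h against 0 h the ranges were 7485 to 8725, 2269 to 2601 up and 5216 to 6124 down, and at 4 h against 1 h 5447 to 6381, 1724 to 2058 and 3676 to 4323; for the lists they were 9 to 12, 13 to 14 and 10 to 12.

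Centring turned the majority of the calls from falls to rises, quantile normalization did not, and neither turned a called change of a named gene. With quantile normalization 3176 rose and 3881 fell at 4 h against 0 h, and 2399 rose and 2694 fell at 4 h against 1 h; with each array centred on its median, 4180 rose and 2894 fell at 4 h against 0 h, and 3456 rose and 2065 fell at 4 h against 1 h. Centring moved the median log2 fold change from -0.22 to 0.03 and from -0.17 to 0.06. With an estimated correlation 7 lists passed at 4 h against 0 h and 0 at 4 h against 1 h (2 at an unadjusted p under 0.05), since camera then widens the variance of lists whose members move together; with the code range as a block as well, 10 passed at 1 h, 0 at 4 h against 0 h (11 unadjusted) and 0 at 4 h against 1 h (5 unadjusted). The 216 probe sets whose response at 4 h differed between code ranges became 326 with a pseudocount of 64, 142 with the ranges 12 to 22 and 32 to 37 alone, 0 with 12 to 22 and 44 to 54 alone (2053 unadjusted), 0 with 32 to 37 and 44 to 54 alone (1866 unadjusted), and 94 without the 2 arrays of highest actin ratio; with all 18 arrays in the fit, pairs of ranges gave 348, 10 and 2 in that order of pairs. The cause of these moves of the count between settings was not tested. Low signal limits what can be said of dim genes. The filter kept 57.3% of probe sets, a share largely set by its use of each array's own median.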

Other observations

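All the tests in this part were chosen after the data were seen. Genes were grouped by the letters that open their symbols, which gave 66 groups of at least 15 tested genes, and falls and rises at 4 h against 0 h were compared with those of all other genes by Fisher's exact test, adjusted over 132 tests. Zinc finger genes of the Zfp series, most of which encode DNA binding proteins, fell more often than others: 117 of 275 fell (42.5%, against 23.4% of other genes; adjusted p = 6.45e-10) and 14 rose. Their median log2 fold change was -0.44, against -0.19 for other genes, and 70.9% of them lay below the median of the others. With quantile normalization 77 of 275 fell (28.0% against 17.2%), and with each array centred on its median 73 (26.5% against 11.2%). Cep genes, most of which encode centrosomal proteins, fell in 18 of 36 cases, 50% against 23.8% of other genes (adjusted p = 0.0169). Under either scaling 10 of 36 fell, 27.8% against 17.4% of other genes with quantile normalization and 11.5% with centring. Nudt genes, which encode hydrolases of nucleotide derivatives, fell in 10 of 18 cases, 55.6% against 23.8% of other genes (adjusted p = 0.0498). With quantile normalization 9 of the Nudt genes fell (50% against 17.4%), and with centring 7 (38.9% against 11.6%). Fam genes, a series named by sequence and not by function, fell in 38 of 103 cases, 36.9% against 23.8% of other genes (adjusted p = 0.0498). With quantile normalization 27 of the Fam genes fell (26.2% against 17.4%), and with centring 22 (21.4% against 11.5%). Their median log2 fold change with quantile normalization was -0.09, against -0.07 for other genes, and 50.5% of them lay below the median of the others. There the share of falls was higher, while the typical Fam gene lay close to the other genes. The shares under quantile normalization and centring were not tested for any group. Atp genes, many of which encode ATPase subunits, fell in 5 of 59 cases, 8.47% against 24% of other genes (adjusted p = 0.0498), but in 20.3% against 17.4% with quantile normalization, so no difference is given for them.

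Collagen genes (symbols that open with Col) fell in 0 of 28 cases, against 23.9% of other genes (Fisher's exact test, adjusted p = 0.0169), and 3 rose by limma. In the fit with the code range as a block 2 fell, 7.14% against 31.9%, and 5 rose. The stromal markers, collagens among them, differed between code ranges by a median of up to 13.8-fold. That widens their spread without a block, so the lack of falls may in part be a lack of calls. Col1a2 had adjusted p = 0.723 by limma without the block and 0.00875 with it. The median log2 fold change of the 28 collagen genes turned from -0.12 to 0.07 with quantile normalization and 0.12 with centring. None of the ribosomal protein genes of the small subunit (26 tested) or of the large subunit (23 tested) fell as deposited, and 1 of each rose (adjusted p = 0.0386 and 0.0498 for falls). Their median log2 fold changes were -0.18 and -0.18, close to the -0.19 of other genes. With each array centred on its median they were 0.06 and 0.06, against 0.05 for other genes. They moved with the other genes, so no direction is given for them. With quantile normalization 2 and 1 fell, and with the code range as a block 4 and 2. Ccl chemokine genes rose in 10 of 15 cases (adjusted p = 4.40e-05) and in 10 of 15 under both other scalings. Genes of a group can share sequence and probe design, so they are not independent of each other.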
